A study of Oncorhynchus mykiss with 10 samples.

How the data were processed

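Muscle RNA from the injection site of 10 clonal rainbow trout was measured on 10 spotted cDNA arrays of salmonid clones, with 1 fish per array. Groups were taken from the sample labels: 3 fish given buffer (PBS), 3 given plasmid vector without the G gene and 4 given the vaccine plasmid. The authors amplified 1.5 µg of sample RNA and 2 µg of reference RNA in 1 round, labelled each sample with Cy3 and the reference pool with Cy5, and used no dye swap, so a dye bias of a clone is shared by all arrays and leaves the differences between groups. Scans were quantified with Agilent Feature Extraction A.7.5.1. Per the file headers, the mean spot signals, the local background signals and the processed signals are in intensity units (pixel brightness). The deposited value table and the scanner's own ratio column are log10 ratios of Cy5 reference over Cy3 sample. On each array the deposited table equalled that column, with a largest difference of 4.69e-08, so its scale, centring and direction are known. Its medians were 0 on 8 arrays, -0.00362 for vector 1 and -0.00678 for vaccine 1.

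All ratios were turned to log2 of Cy3 sample over Cy5 reference, so that a positive value means more RNA in the muscle sample than in the pool. Mean signals were corrected for the median local background with normexp (offset 50), normalized by loess within each array with control spots at weight 0, and stripped of spots the scanner software had marked as outliers, which were 8.18% to 32.2% of clone spots. The 32 clones spotted more than once were averaged. Of 15964 clones, 15883 were well above background in the Cy3 channel on all arrays of at least 1 group, and the 12422 that also had at least 2 unmarked arrays in each group were tested. Blank spots were called well above background on 19.3% to 57.0% of their number, so this filter removed few dim clones. A filter against the 95th percentile of the blank spots was added after the data had been seen.

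One linear model with a mean per group was fitted over the 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p values were adjusted by Benjamini-Hochberg within each of the 3 comparisons, with a threshold of 0.05. Errors of log2 fold changes are the standard errors of that model. Clones are named by the accession and description in the array's own annotation, which can be old. The reference table of gene symbols held none (0) of the 12422 accessions, so no name was updated. Of 15996 clone spots, 6806 were described as unknown and 6321 had a usable gene name.

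The 20 gene lists (interferon-induced antiviral genes, MHC class I presentation, MHC class II presentation, chemokines and cytokines, complement, acute phase and iron, phagocytes, T and NK cells, B cells, erythrocytes, liver, skeletal muscle contractile genes, fibroblasts and extracellular matrix, adipocytes, glycolysis, oxidative phosphorylation, ribosomal proteins, proteasome core and cap, cell cycle, apoptosis) were matched by description, with mismatches removed by name alone before any fit, and no tested clone belonged to more than 1 list. Each list was compared with all other tested clones by limma's camera with a preset correlation between clones of 0.01. Because that function takes no missing values, its version for precomputed statistics (cameraPR) was run on normal scores of the moderated statistics. The 60 gene list tests were adjusted together. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other clones, were run on values that kept the outlier spots. Named clones were chosen by a rule: per comparison, the 12 largest rises and the 12 largest falls among named clones that passed the test with no overlap between the groups' values, 1 clone per name, plus up to 4 members of each list with the smallest p in vaccine versus PBS. A clone named outside this rule is said to have been chosen after its value was seen.

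Groups, tests, filter, lists, rule and most alternatives were chosen before the data were examined. The alternatives were no background correction, plain background subtraction with the scanner's dye correction, the deposited table, an offset of 10, median centring without loess, quantile scaling of average intensity after loess, the Cy3 channel alone with quantile scaling, other spot filters, a trended and robust prior, array weights, fits of only the compared groups, the replicate number as a block, outlier spots kept, other thresholds, 1 value per gene name for the lists, and leaving out each array in turn. Those added after the data had been seen were the blank-spot filter, loess within the 48 print blocks, and leaving out vector 1 and vaccine 3 together. Fits that left out an array kept the tested clones fixed and accepted 1 unmarked array per group, so a lone array was assumed to vary like the other groups. The same model was tested on simulated data with 200 changed clones of 12422: it recovered 83% and 85% of 2-fold changes and 37% and 38.5% of 1.5-fold changes in the comparisons of the vaccine group with PBS and vector, with none (0) in the wrong direction. A simulated shift of 0.5 on the log2 scale in the phagocyte list was found, and 0 of the 19 other lists passed. The simulated noise was independent between clones, so these simulations do not show how the tests behave when clones vary together. The number of arrays limits the precision of every value.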

Results

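The data describe gene expression in skeletal muscle 7 days after an injection of 50 µL below the dorsal fin of clonal rainbow trout (Hot Creek line, males about 1 year old). The fish received PBS (n = 3), 10 µg of an empty plasmid vector (n = 3) or 10 µg of a DNA vaccine (n = 4) whose plasmid carries the glycoprotein (G) gene of infectious hematopoietic necrosis virus, a rhabdovirus of salmon and trout. Every sample was compared with the same reference pool, made of anterior kidney, spleen, liver and muscle RNA of 3 unhandled fish, and values are log2 ratios of sample to pool. The median Cy3 signal of clone spots was 808 to 1542 units per array, or 3.59 to 6.24 times the local background, and the median Cy5 signal was 1940 to 2669 units. The direction of the ratio was checked on tissue genes in PBS fish: the median of the skeletal muscle list was 3.27 ± 0.14 (SD, n = 3), and those of the liver and erythrocyte lists were -4.07 ± 0.35 and -2.99 ± 0.10. Across clones, which are not independent replicates, PBS arrays correlated with each other at r of 0.975 to 0.981, vector arrays with PBS arrays at 0.848 to 0.967, and vaccine arrays with PBS arrays at 0.783 to 0.907.

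The first comparison asks what the vaccine changed at the injection site against buffer alone. The largest rise was that of VHSV-induced protein-3 (CB499972), a clone of the interferon list. The gene, named for its induction by the related viral hemorrhagic septicemia virus (VHSV), went from a log2 ratio of -2.68 ± 0.11 (SD, n = 3) in PBS fish to 3.71 ± 0.19 (SD, n = 4) in vaccine fish, an 84.0-fold rise. Clones of antigen presentation, B and T lymphocytes and phagocytes rose too, and clones of mitochondrial respiration, glycolysis and muscle contraction fell. With an estimated correlation between clones the interferon list was the 1 of 20 lists to pass in this comparison, and the muscle list also did not pass with the Cy3 channel alone.

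By limma, 5863 of 12422 tested clones (47.2%) differed between vaccine and PBS fish at an adjusted p under 0.05, 2298 higher and 3565 lower. At least 2-fold changes numbered 810 up and 446 down, so the larger changes were mostly rises: the log2 fold changes reached 6.39 upward and -2.85 downward. The groups' values did not overlap for 57% of all tested clones, where chance gives 5.71%. The median over all clones was -0.09 and moved to -0.12 when arrays were centred on their median without loess, and changes are relative to it. With the Cy3 channel taken alone the count was 2734, 1257 higher and 1477 lower. Of the 129 clones picked by the rule for named genes, 123 passed in this comparison, 93 of them under each of the 27 alternatives run on single clones, and 28 were lost with the Cy3 channel alone.

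**Figure D1:**
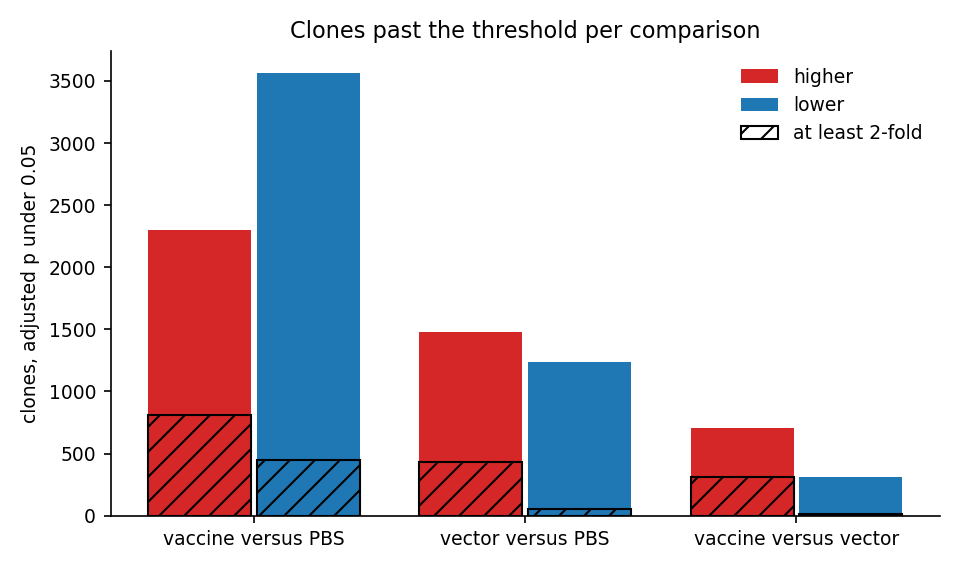
Clones past an adjusted p of 0.05 in each comparison of groups (bars, number of clones; hatched part, at least 2-fold). Vaccine versus PBS has 2298 higher and 3565 lower clones, vector versus PBS 1481 and 1240, and vaccine versus vector 708 and 315.

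The interferon list held 33 tested clones, of which 29 rose and 3 fell in vaccine against PBS fish, with the same counts when adjusted over the list alone. Its median log2 fold change was 1.84 (adjusted p = 5.36e-20, and adjusted p = 0.0408 with an estimated correlation). Over the 30 alternatives run on lists its adjusted p lay between 3.45e-24 and 0.0408. The estimated correlation gave the highest adjusted p for 35 of the 40 list calls made in the 3 comparisons, and left 3 of the 40. Fry, which tests whether a list moves one way without comparing it with other clones, called 29 of the 60 list tests, 25 of them among the 40. VHSV-induced protein-4 (CA051350) rose 45.8-fold (log2 5.52 ± 0.12, SE, n = 4 and 3; adjusted p = 5.18e-10) and VIG-2 (CB498642), another gene found through VHSV infection, 35.0-fold (adjusted p = 1.79e-07). Galectin 3 binding protein (CB515011), a secreted glycoprotein, rose 16.1-fold. Outside the list, urokinase receptor (CA057830) rose 42.7-fold, and cyclin-E binding protein 1 (CA052560), known in mammals as a ligase for the ubiquitin-like protein ISG15, 24.7-fold. Of the 5 clones described only as VHSV-induced protein, 4 rose and 1 fell. A ubiquitin clone (CB515535) rose 11.9-fold, but it was 1 of 5 clones of that name to rise.

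Antigen presentation genes rose in both classes. Of 61 clones for MHC class I presentation, which displays peptides from inside the cell to cytotoxic T cells, 49 rose and 1 fell, the same when adjusted over the list alone (median log2 2.26, adjusted p = 1.6e-28, and adjusted p = 0.108 with an estimated correlation). Low molecular mass protein 2 (CA051372), a subunit of the immunoproteasome, went from -2.12 ± 0.11 (SD, n = 3) to 0.85 ± 0.20 (SD, n = 4), a 7.87-fold rise. Beta-2 microglobulin (CB505897), the light chain of class I molecules, rose 5.57-fold and tapasin (CB509439), which helps to load peptides on class I molecules, 4.75-fold. Of 33 clones for MHC class II presentation, which displays peptides taken up from outside, 29 rose and 1 fell, also over the list alone (median log2 2.11, adjusted p = 4.47e-16, and adjusted p = 0.286 with an estimated correlation). Invariant chain INVX (CK990275), of the family of class II chaperones, rose 5.58-fold, and interferon gamma-inducible protein 30 (CA058205), a lysosomal thiol reductase that unfolds antigens, 8.42-fold.

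Markers of immune cells rose as well. Of 47 B cell clones, nearly all for immunoglobulin chains, 39 rose and 2 fell (median log2 1.44, adjusted p = 5.36e-20, and adjusted p = 0.0745 with an estimated correlation), with the same counts over the list alone. Ig light chain (CK990633) rose 7.19-fold, from -4.47 ± 0.09 (SD, n = 3) to -1.62 ± 0.19 (SD, n = 4), and immunoglobulin heavy chain (CB506793) 4.70-fold. Of 11 T and NK cell clones 7 rose, also over the list alone (median 0.52, adjusted p = 0.000231, and adjusted p = 0.0502 with an estimated correlation). T-cell receptor alpha chain (CB498619) rose 4.55-fold and T-cell receptor beta chain (CA042023) 3.03-fold. Of 50 phagocyte clones 38 rose and 1 fell, also over the list alone (median 1.31, adjusted p = 4.56e-13, and adjusted p = 0.313 with an estimated correlation). Among them lysozyme CII (CA054167), which breaks bacterial cell walls, rose 8.39-fold, lysozyme g (CN442504) 5.92-fold and L-plastin (CA040383), an actin-bundling protein of leukocytes, 4.01-fold.

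Genes of muscle energy metabolism and contraction went the other way. Of 216 clones for oxidative phosphorylation 146 fell and 8 rose, 148 and 9 when adjusted over the list alone (median log2 -0.71, adjusted p = 5.88e-09, and adjusted p = 0.538 with an estimated correlation). NADH dehydrogenase Fe-S protein 8 (CB512307), of respiratory complex I, fell by 0.99 ± 0.11 (SE) and ubiquinol-cytochrome c reductase core protein II (CA041460), of complex III, by 1.26 ± 0.14. Of 61 glycolysis clones 32 fell and 1 rose, 34 and 1 over the list alone (median -0.61, adjusted p = 6.8e-05, and adjusted p = 0.63 with an estimated correlation). Enolase 2 (CA059991) fell by 1.29 and alpha enolase (CB503486) by 1.12, while a pyruvate kinase clone (CA051402) rose 3.11-fold in a name whose 6 clones gave 1 rise and 2 falls. Of 115 clones for skeletal muscle contractile genes 43 fell and 1 rose, 35 and 1 over the list alone (median -0.64, adjusted p = 6.8e-05, and adjusted p = 0.65 with an estimated correlation). With the Cy3 channel alone this median was -0.07 and the adjusted p was 0.147 (3.92e-09 to 0.65 over the alternatives). With fry the list did not pass either (adjusted p = 0.0731). Myosin light chain 2 (CB511383) fell by 1.22 ± 0.23 (SE, n = 4 and 3) and cardiac tropomyosin (CB509084) by 1.11, calls that ended with the Cy3 channel alone. The fall of heart-type fatty acid binding protein (CB497827), which carries fatty acids in muscle, by 2.35 ± 0.38 held there.

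**Figure D2:**
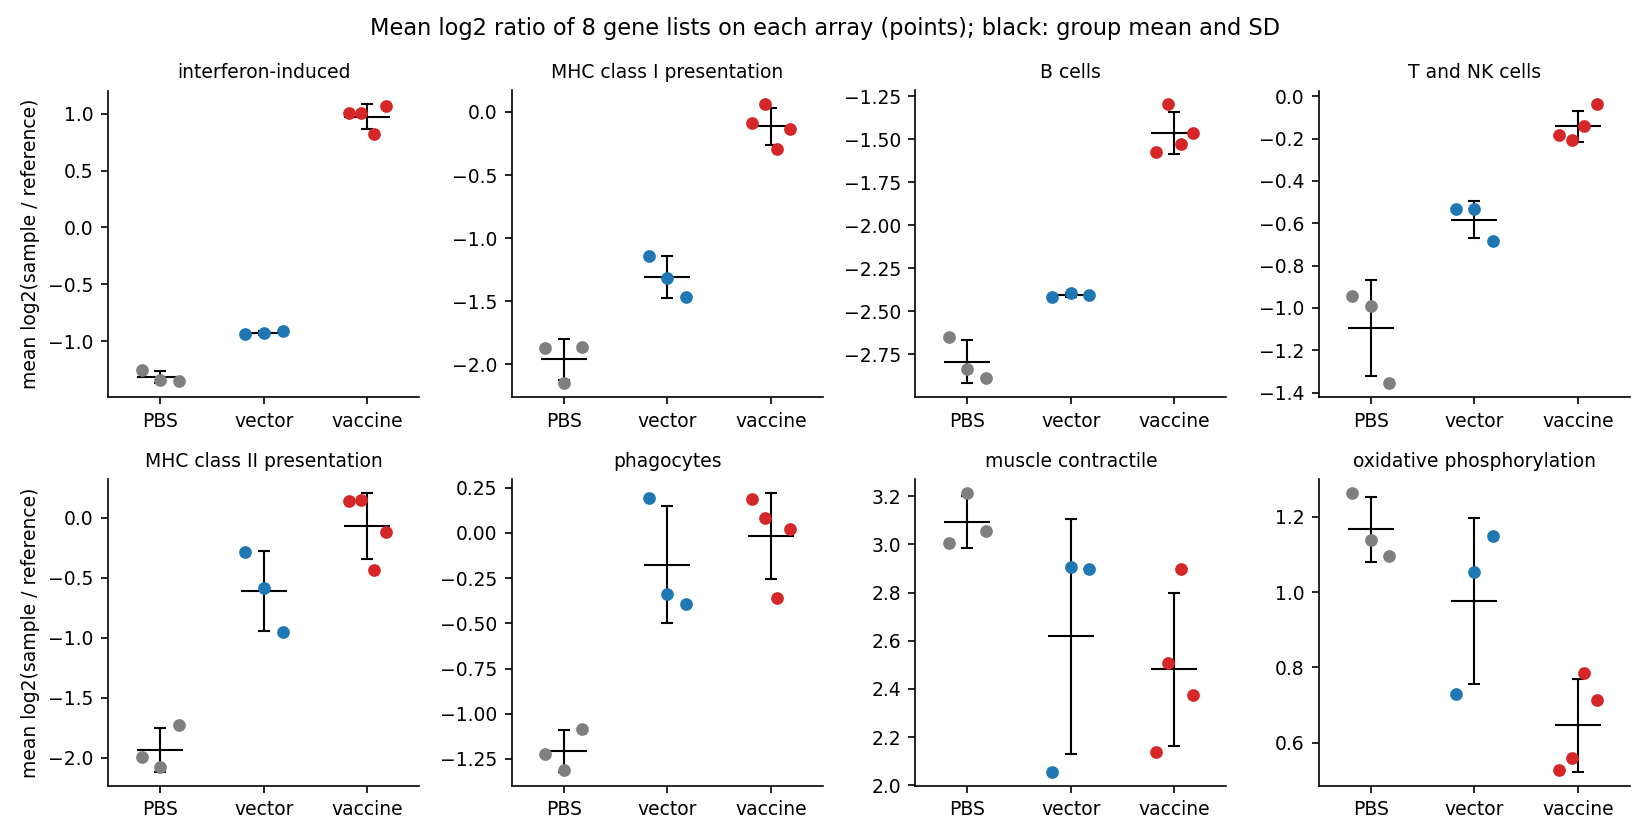
Mean log2 ratio of sample to reference pool over the clones of 8 gene lists, per array (points) in the PBS, vector and vaccine groups, with each group's mean and SD in black. The interferon list means lie between 0.82 and 1.07 on the vaccine arrays and between -0.94 and -0.91 on the vector arrays.

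In the liver and complement lists more clones fell than rose in vaccine against PBS fish. Of 65 clones for liver genes 32 fell and 2 rose, 33 and 3 over the list alone (median -0.66, adjusted p = 0.000144, and adjusted p = 0.63 with an estimated correlation). The liver median was -0.335 with the Cy3 channel alone. Apolipoprotein B (CA048599), of lipoprotein particles, fell by 0.91, although another clone of its name rose, and alpha-2-macroglobulin-1 (CB509867), a protease inhibitor, by 1.58. Of 37 complement clones 16 fell and 3 rose, also over the list alone (median -0.36, adjusted p = 0.0163, and adjusted p = 0.65 with an estimated correlation). The complement call also ended with the scanner's own ratio (adjusted p = 0.0734), median centring (0.225), the Cy3 channel alone (0.619), the replicate number as a block (0.0528) and 1 value per gene name (0.132), in a range of 0.00299 to 0.65. Complement factor Bf-2 (CB509524) fell by 1.54, and C-type mannose-binding lectin (CB507038), which binds microbial sugars, by 0.72 in a name whose 5 clones gave 3 falls and 1 rise. MASP-2 (CA061305), a protease that works with such lectins, rose 2.20-fold. Of 58 clones for acute phase and iron genes 29 rose and 13 fell, 29 and 14 over the list alone (median 0.57, adjusted p = 0.00162, and adjusted p = 0.313 with an estimated correlation). Ferritin heavy subunit (CB498077), which stores iron, rose 2.38-fold, and with 1 value per gene name the list did not pass (adjusted p = 0.894, in a range from 0.000117).

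The proteasome list, without the immune subunits, had 19 of 55 clones up and 5 down, 19 and 4 over the list alone (median 0.40, adjusted p = 6.93e-05, and adjusted p = 0.63 with an estimated correlation or 0.064 with fry). Proteasome subunit N3 (CA055298) rose 4.35-fold. The list of ribosomal proteins, 400 clones, had 44 up and 30 down, 15 and 12 over the list alone. Its median of 0.07 was 0.04 without PBS 1 or without vaccine 4 and turned to -0.14 under median centring (adjusted p = 0.0767). Its call (adjusted p = 0.0172) ended with an estimated correlation (adjusted p = 0.65), without PBS 1 (0.124), without vaccine 4 (0.0867), with the scanner's own ratio (0.263), the Cy3 channel alone (0.705), outlier spots kept (0.355), the replicate number as a block (0.0955), fry (0.225) and loess within print blocks, chosen after seeing the data (0.0588), in a range from 0.00154. The other lists did not pass, but fry called 3 of them, all downward. Chemokines and cytokines had 3 of 16 clones up and 10 down, also over the list alone (median -0.57, adjusted p = 0.123, and 0.00217 with fry): a chemokine receptor homolog (CA048961) rose 2.53-fold and interleukin 1 receptor accessory protein (CB516412) fell by 0.89. Apoptosis genes had 4 of 24 up and 9 down (adjusted p = 0.442, and 9.62e-05 with fry), among them Bcl-G (CA052247), of the Bcl-2 family, up 2.34-fold and programmed cell death 5 (CB515837) down by 0.84. Cell cycle genes had 1 of 29 up and 8 down (adjusted p = 0.907, with a median of -0.04 that turned to 0.0055 without background correction). Fibroblast and matrix genes had 1 of 45 up and 4 down (0 and 2 over the list alone; adjusted p = 0.704, with a median of -0.14 that turned to 0.01 with the Cy3 channel alone). Erythrocyte genes had 1 of 21 up (adjusted p = 0.363) and adipocyte genes 1 of 3 up and 2 down (0.596, and 0.0206 with fry).

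The second comparison asks what the plasmid did without the G gene. Among the lists, those of MHC class II presentation and phagocytes had the highest medians in vector against PBS fish, and the interferon genes that had risen 20-fold or more with the vaccine moved little. Interferon gamma-inducible protein 30 (CA058205) rose 5.58-fold, from -1.02 ± 0.30 (SD, n = 3) to 1.46 ± 0.45 (SD, n = 3), and lysozyme CII (CA054167) 5.40-fold. Cathepsin K (CB512534), a lysosomal protease, rose 4.71-fold, a 16 kDa subunit of the vacuolar proton pump (CB514424) 4.49-fold, and cystatin B (CK990493), an inhibitor of cathepsins, 5.41-fold. The largest rise of a named clone was that of N-acetylneuraminic acid phosphate synthase (CB488963), which makes sialic acid, at 6.47-fold. VHSV-induced protein-3 had a log2 fold change of 0.20 ± 0.13 (SE, adjusted p = 0.26).

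By limma, 2721 of 12422 clones (21.9%) differed between vector and PBS fish, 1481 higher and 1240 lower. At least 2-fold changes numbered 434 up and 52 down. The groups' values did not overlap for 48% of tested clones, where chance gives 10% for a clone with no array marked and more for the others. The count was 1413 without PBS 1, 1295 without PBS 2, 1343 without vector 1 and 693 with the Cy3 channel alone, and the share of rises, 54.4%, was 65.9%, 65.4%, 65.5% and 71.4% in these fits. Of 84 named clones that passed, 33 did so under each of the 27 alternatives, and 45 were lost with the Cy3 channel alone.

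Of 50 phagocyte clones 33 rose, 35 up and 1 down over the list alone (median log2 1.23, adjusted p = 6.07e-14, and adjusted p = 0.313 with an estimated correlation). L-plastin (CA040383) rose 2.58-fold and lysozyme g (CN442504) 3.09-fold. Of 33 MHC class II clones 29 rose and 1 fell, also over the list alone (median 1.52, adjusted p = 2.74e-17, and adjusted p = 0.286 with an estimated correlation), with invariant chain INVX (CK990275) up 3.00-fold and MHC class II invariant chain-like protein 2 (CB511419) 3.82-fold. Of 61 MHC class I clones 37 rose and 1 fell, 41 and 2 over the list alone (median 0.77, adjusted p = 1.94e-15, and adjusted p = 0.286 with an estimated correlation). Beta-2 microglobulin (CB505897) rose 2.01-fold to -1.99 ± 0.20 (SD, n = 3). Of 47 B cell clones 20 rose, 25 up and 2 down over the list alone (median 0.42, adjusted p = 2.06e-07, and adjusted p = 0.313 with an estimated correlation), and Ig light chain (CK990633) rose 2.05-fold. Of 11 T and NK cell clones 5 rose, 6 over the list alone (median 0.33, adjusted p = 0.00178, and adjusted p = 0.0721 with an estimated correlation), with T-cell receptor alpha chain (CB498619) up 2.01-fold. The interferon list had 13 of 33 clones up and 2 down, 14 and 4 over the list alone (median 0.20, adjusted p = 0.000573, and adjusted p = 0.313 with an estimated correlation).

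Of 216 oxidative phosphorylation clones 26 fell and 7 rose, 12 and 6 over the list alone (median -0.26, adjusted p = 0.00241, and adjusted p = 0.741 with an estimated correlation), and the list did not pass without vector 1 (adjusted p = 0.127), without vector 1 and vaccine 3, chosen after seeing the data (0.132), or with fry (0.248), in a range of 2.25e-05 to 0.741. Glycolysis had 10 of 61 clones down and 3 up, 14 and 3 over the list alone (median -0.40, adjusted p = 0.000533, and adjusted p = 0.65 with an estimated correlation or 0.178 with fry). Of 115 muscle contractile clones 10 fell, and none (0) when adjusted over the list alone (median -0.42, adjusted p = 8.78e-06, and adjusted p = 0.65 with an estimated correlation or 0.17 with fry). The muscle median was -0.11 with the Cy3 channel alone (quartiles -0.41 and 0.008). The list mean was 3.01 to 3.21 on the PBS arrays, 2.06 on vector 1, 2.91 on vector 2 and 2.90 on vector 3. Without vector 1 the medians were -0.20 for muscle, -0.26 for glycolysis, -0.09 for oxidative phosphorylation and -0.36 for liver genes, and without PBS 1 they were -0.25 for glycolysis and -0.17 for oxidative phosphorylation. Liver genes had 17 of 65 clones down, 20 over the list alone (median -0.58, adjusted p = 1.86e-06, and adjusted p = 0.509 with an estimated correlation or 0.0518 with fry), with apolipoprotein B (CA048599) down by 0.77. The liver median was -0.239 with the Cy3 channel alone. Complement had 11 of 37 down and 4 up, 12 and 4 over the list alone (median -0.29, adjusted p = 0.0103, and adjusted p = 0.63 with an estimated correlation). Its call ended with median centring (adjusted p = 0.168), the Cy3 channel alone (0.613), fry (0.0635) and 1 value per gene name (0.139), in a range from 0.00328.

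Acute phase and iron genes had 13 of 58 clones up and 2 down, 17 and 4 over the list alone (median 0.34, adjusted p = 0.00133, and adjusted p = 0.313 with an estimated correlation, or 0.709 with 1 value per gene name), with ferritin heavy subunit (CB498077) up 2.21-fold. The proteasome list had 17 of 55 up, 23 over the list alone (median 0.47, adjusted p = 1.03e-07, and adjusted p = 0.509 with an estimated correlation or 0.0518 with fry), and its median was 0.24 without vector 1. Ribosomal proteins had 18 of 400 up and 2 down, 2 and 0 over the list alone (adjusted p = 0.000198, and adjusted p = 0.509 with an estimated correlation), and the median of 0.10 turned to -0.0052 with the Cy3 channel alone. That call ended with the Cy3 channel alone (adjusted p = 0.288), the scanner's own ratio (0.122), fry (0.0644) and median centring (0.588), in a range from 2.57e-06. Chemokines and cytokines had 6 of 16 down and 1 up, 8 and 2 over the list alone (median -0.36, adjusted p = 0.0186, and adjusted p = 0.352 with an estimated correlation). That call ended with median centring (adjusted p = 0.146), the Cy3 channel alone (0.13), outlier spots kept (0.213) and 1 value per gene name (0.11), in a range from 0.00377. Fibroblast and matrix genes had 8 of 45 up and 3 down, 8 and 4 over the list alone, and passed narrowly (median 0.14, adjusted p = 0.05 after rounding, and adjusted p = 0.65 with an estimated correlation). They did not pass without PBS 2 (0.0628), PBS 3 (0.171), vector 2 (0.155) or vaccine 2 (0.0575). Their call also ended with an offset of 10 (0.0526), no filter on dim spots (0.0502), a trended and robust prior (0.113), fry (0.248), 1 value per gene name (0.38) and loess within print blocks (0.0848, chosen after seeing the data), in a range from 0.0137. Their median was 0.07 without PBS 3 and 0.08 without vector 2. Apoptosis genes (2 of 24 up and 7 down, adjusted p = 0.168, and 0.0355 with outlier spots kept or 0.000335 with fry), erythrocyte genes (median 0.63, adjusted p = 0.123, and 0.0419 without vaccine 1, 0.0169 with the Cy3 channel alone, 0.0466 with the replicate number as a block or 0.00683 with the compared groups alone, in a range up to 0.894), adipocyte genes (0.927, with a median of -0.30 against a mean of 0.12) and cell cycle genes (0.895, with a median of -0.0086 but a test pointing up) did not pass.

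Most clones called with the vector were also called with the vaccine. Of the clones higher with the vector 82.7% were also higher with the vaccine, and of those lower with the vector 93.5% were also lower, among them lysozyme CII and cathepsin K on the one side and apolipoprotein B on the other. Of those higher with the vaccine 53.3% were also higher with the vector, and of the 3565 lower with the vaccine 1159 were also lower. In numbers, 1225 clones rose with both plasmids, 1159 fell with both and 15 went opposite ways, and both comparisons use the same PBS arrays. The log2 fold changes of the plasmids against PBS correlated across clones at r = 0.797, and simulated groups with no change that share the PBS arrays gave 0.529 ± 0.015 (SD, 100 draws). The simulated clones varied independently, so this SD does not measure how far r could vary by chance on real arrays. The covariance of the fold changes, planned beside r, was 0.264, where the simulated groups gave a mean of 0.0183. Clones are not independent replicates, and 3 PBS arrays were too few to give each plasmid its own controls.

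**Figure D3:**
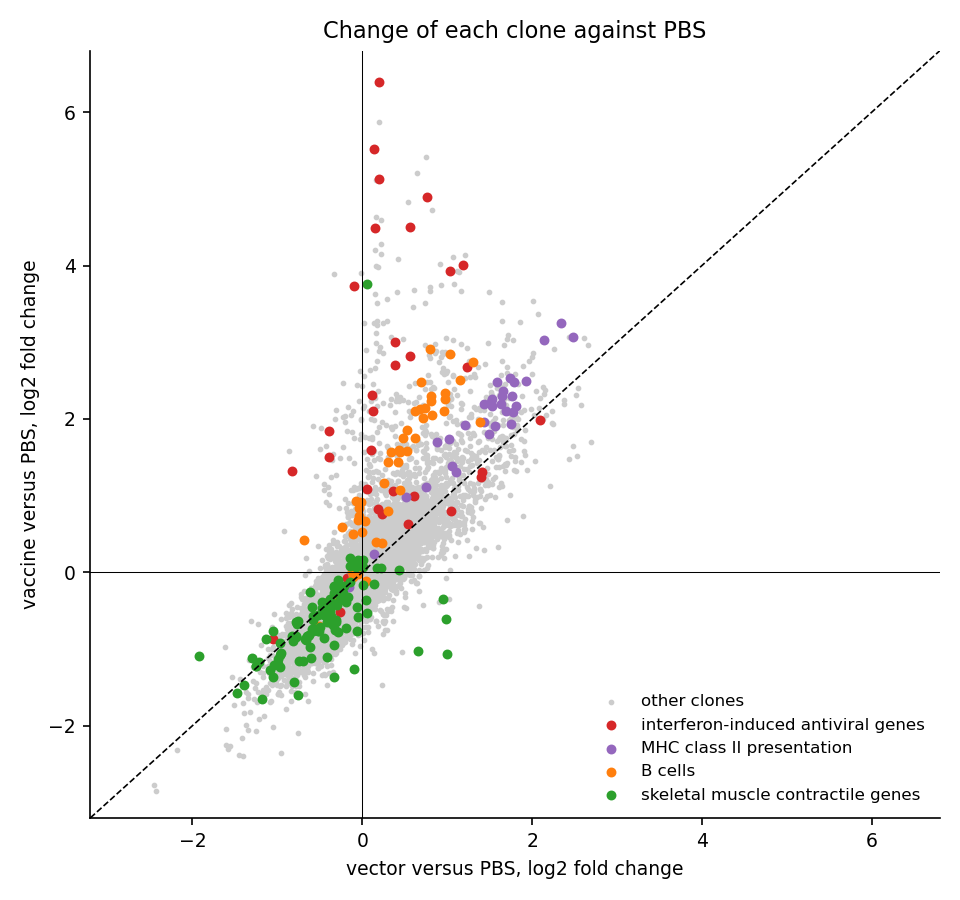
Log2 fold change of each tested clone in vaccine versus PBS (vertical axis) against vector versus PBS (horizontal axis), with the clones of several gene lists coloured. Many clones of the interferon list stand far above the line of equal change, where VHSV-induced protein-3 reaches 6.39 against 0.20. Of the 33, 24 were higher in vaccine than in vector fish and 9 were not called, with a lower quartile of 0.185, so some lie near the line.

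The third comparison asks what the G gene added to the plasmid. The interferon genes set the vaccine fish apart: VHSV-induced protein-3 (CB499972) was 73.0-fold higher in vaccine than in vector fish (log2 6.19 ± 0.12, SE, n = 4 and 3), VHSV-induced protein-4 (CA051350) 41.7-fold and VIG-2 (CB498642) 30.6-fold. Clones of immunoglobulin and class I presentation were higher too: Ig light chain (CK990633) rose 3.51-fold, from -3.43 ± 0.08 (SD, n = 3) to -1.62 ± 0.19 (SD, n = 4), and beta-2 microglobulin (CB505897) 2.78-fold. The class I list as a whole did not pass with an estimated correlation (adjusted p = 0.0502). Phagocyte markers differed little, with lysozyme CII (CA054167) at a log2 fold change of 0.64 ± 0.30 (SE, adjusted p = 0.232).

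By limma, 1023 of 12422 clones (8.24%) differed, 708 higher and 315 lower in vaccine fish, and at least 2-fold changes numbered 313 up and 16 down. The groups' values did not overlap for 23.3% of tested clones, where chance gives 5.71% for a clone with no array marked and more for the others. The count was 1730 without vector 1, 647 without vector 2, 635 without vector 3, 370 with the Cy3 channel alone and 2622 with array weights, and the share of rises, 69.2%, ranged in these fits from 43.2% with array weights to 92.2% with the Cy3 channel alone. On several lists vector 1 lay apart from its group and vaccine 3 at the edge of its own, as the list means per array show. On the muscle list vector 1 was at 2.06 and vaccine 3 at 2.90, where the other vaccine arrays were at 2.14 to 2.51. Vector 1 and vaccine 3 also stood out in median Cy3 signal, at 1542 and 1050 units. The other vaccine arrays had 1237 to 1505, the other vector arrays 1125 and 1223, and the PBS arrays 808 to 1179. Signal thus differed along with the list means, and its part in them was not tested. By Dixon's test, given below, no list mean of the vaccine arrays was an outlier (share 0.516 for vaccine 3 on the muscle list). Vector 1 was not tested this way, since the test was run on the vaccine group only. Leaving out vector 1 and vaccine 3 together, an alternative chosen after seeing the data, gave 2915 clones. Of 58 named clones that passed, 34 did so under each of the 27 alternatives, 22 were lost with the Cy3 channel alone and 18 without at least 1 array.

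Of 33 interferon clones 24 rose and none (0) fell, the same over the list alone (median log2 1.90, adjusted p = 2.51e-32, and adjusted p = 0.0219 with an estimated correlation). Of 61 MHC class I clones 43 rose, 49 over the list alone (median 1.51, adjusted p = 3.16e-44, and adjusted p = 0.0502 with an estimated correlation), with low molecular mass protein 2 (CA051372) up 4.35-fold and tapasin (CB509439) 3.41-fold. Of 47 B cell clones 35 rose, 37 over the list alone (median 1.05, adjusted p = 6.12e-35, and adjusted p = 0.0408 with an estimated correlation), with immunoglobulin heavy chain (CB506793) up 2.68-fold. Of 11 T and NK cell clones 6 rose, 6 up and 1 down over the list alone (median 0.49, adjusted p = 0.000344, and adjusted p = 0.0502 with an estimated correlation). T-cell receptor alpha chain (CB498619) rose 2.27-fold, and granzyme K (CB514320), a protease of cytotoxic cells, had a log2 fold change of -0.0045 ± 0.093 (SE, adjusted p = 0.985). Of 33 MHC class II clones 2 rose, 14 over the list alone (median 0.56, adjusted p = 2.26e-09, and adjusted p = 0.365 with an estimated correlation or 0.0518 with fry). Of 50 phagocyte clones 5 rose, also over the list alone (median 0.13, adjusted p = 0.00411, and adjusted p = 0.65 with an estimated correlation), among them granulin-a (CA057393), a growth factor precursor, up 2.54-fold. The phagocyte call ended without vector 2 (adjusted p = 0.0651) or vector 3 (0.138) and with fry (0.303), in a range of 1.53e-10 to 0.65. The phagocyte median was 0.31 without vector 1, 0.19 without vaccine 3, 0.03 without vector 2, vaccine 1 or vaccine 2, and turned to -0.0038 without vector 3.

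**Figure D4:**
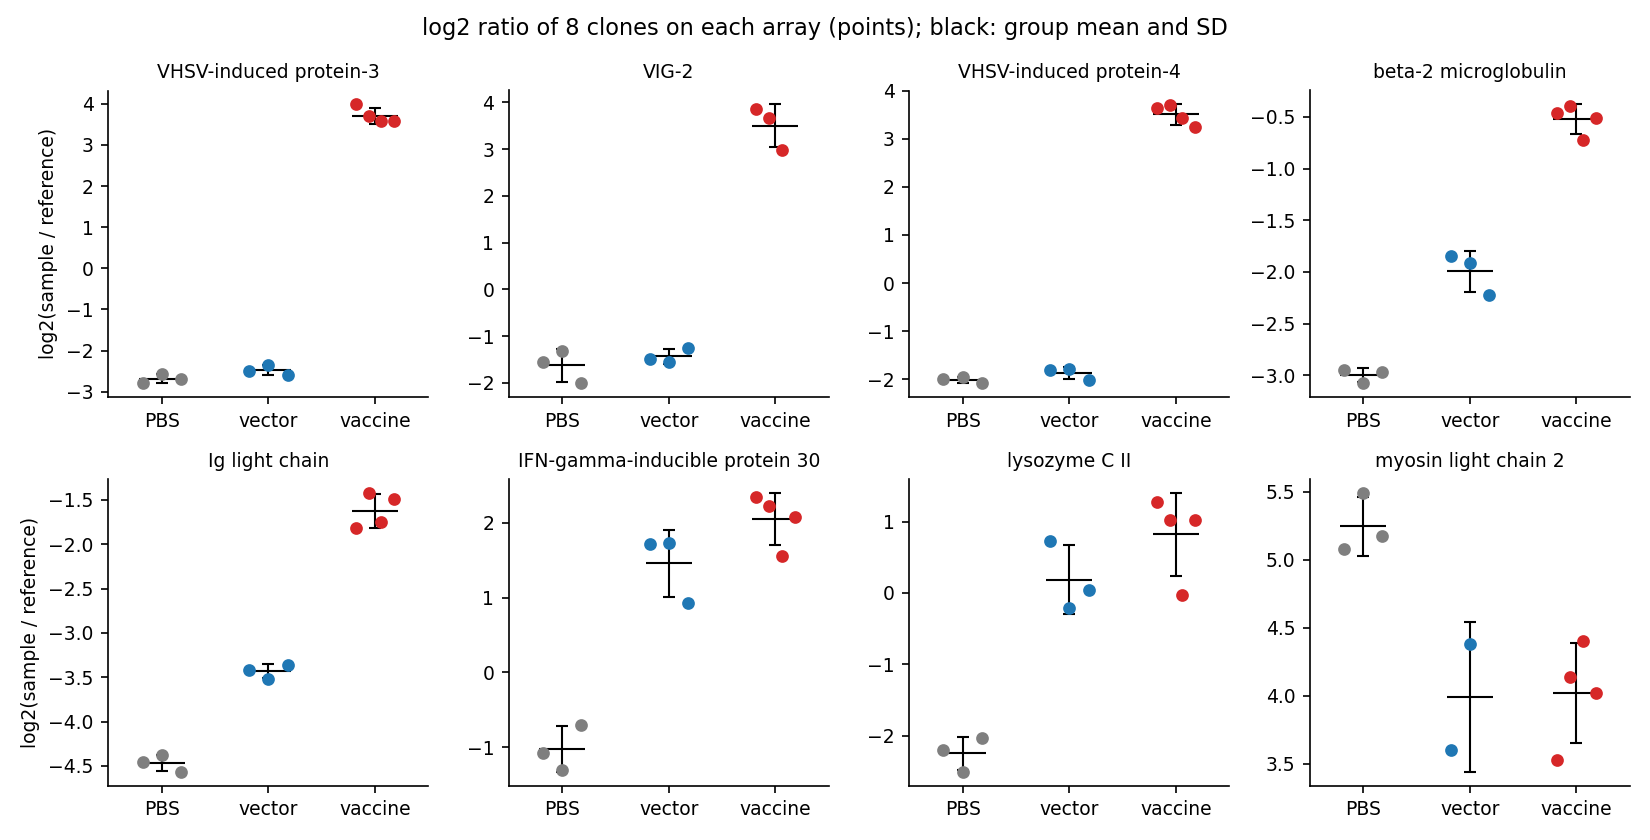
Log2 ratio of sample to reference pool for 8 named clones, per array (points) in the PBS, vector and vaccine groups. Ig light chain averages -4.47 in PBS, -3.43 in vector and -1.62 in vaccine fish, while VHSV-induced protein-3 averages -2.68, -2.48 and 3.71.

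Of 216 oxidative phosphorylation clones 15 fell and 2 rose, 86 and 2 over the list alone (median -0.43, adjusted p = 8.96e-13, and adjusted p = 0.498 with an estimated correlation). Of the 2 that rose, CA051957 (log2 2.73) carries the name of a subunit whose 1 other clone did not rise. The other, CA043649, for cytochrome c oxidase subunit IV and named after its value was seen, rose by 0.77. CA060650, named as cytochrome c oxidase subunit Vb, also rose (log2 3.93), but its description was not matched by the list. Intestinal fatty acid binding protein (CA044478) fell by 1.12 ± 0.14 (SE, n = 4 and 3), S100-like calcium binding protein (CK990568) by 0.92 and the regulatory myosin light polypeptide 9 (CA048073) by 0.89. Fibroblast and matrix genes had 3 of 45 clones down and 1 up, also over the list alone (median -0.32, adjusted p = 0.00178, and adjusted p = 0.509 with an estimated correlation), and did not pass with the Cy3 channel alone (adjusted p = 0.0575) or with 1 value per gene name (0.0964), in a range from 0.000211. Glycolysis had 1 of 61 clones up and none (0) down, 0 and 0 over the list alone (median -0.22, adjusted p = 0.0229, and adjusted p = 0.808 with an estimated correlation), and did not pass without vector 2 (0.128), vector 3 (0.253) or vaccine 1 (0.347), with fry (0.346) or with 1 value per gene name (0.117), in a range from 5.04e-06. The glycolysis median was -0.41 without vector 1, -0.34 without vaccine 3, and -0.10 without vector 3 or vaccine 1. Acute phase and iron genes had 2 of 58 up, none (0) over the list alone, and passed narrowly (median 0.11, adjusted p = 0.05 after rounding, and adjusted p = 0.509 with an estimated correlation). They did not pass without PBS 1 (0.0584), PBS 3 (0.0558), vector 2 (0.128), vector 3 (0.138), vaccine 1 (0.0632), vaccine 2 (0.151) or vaccine 4 (0.118). Nor did they pass with an offset of 10 (0.053), median centring (0.318), the Cy3 channel alone (0.107), no filter on dim spots (0.0502), the compared groups alone (0.0535), the replicate number as a block (0.0724), fry (0.248) or 1 value per gene name (0.924), in a range from 0.000145. Their median was 0.22 without vector 1 or vaccine 3 and 0.07 without vector 3.

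The muscle contractile list had 1 of 115 clones up in vaccine against vector fish (median -0.11, which turned to 0.0093 with the Cy3 channel alone; adjusted p = 0.424). It passed without vector 1 (adjusted p = 7.81e-05), without vaccine 3 (0.00565), without both (5.37e-09, chosen after seeing the data), with array weights (0.000398) and with median centring (0.0258), in a range up to 0.977. Liver genes had 1 of 65 up (adjusted p = 0.72, and 0.0276 without vector 1, 0.0466 without vaccine 3, 0.000145 without both or 0.029 with array weights, in a range up to 0.985). The proteasome list had 1 of 55 up and 1 down (median -0.08, adjusted p = 0.957), passed upward without vector 1 (0.0043) and without both vector 1 and vaccine 3 (0.00137), and downward without vector 3 (0.0355). Erythrocyte genes (adjusted p = 0.895, and 0.0391 without vaccine 1), complement (0.564, and 0.0432 without both vector 1 and vaccine 3), ribosomal proteins (0.564, and 0.000101 downward under median centring), chemokines and cytokines (0.907, with a median of -0.12 but a mean of 0.0096 and a test pointing up), cell cycle (0.391), apoptosis (0.907) and adipocyte genes (0.258) did not pass.

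The last comparison asks which clones differed in vaccine fish from both controls, whether or not the empty plasmid also changed them. Against both controls 662 clones were higher and 228 lower in vaccine fish, 890 in all, and both comparisons use the same vaccine arrays. The interferon genes named above, beta-2 microglobulin, low molecular mass protein 2 and the Ig chains were among the higher ones, and intestinal fatty acid binding protein among the lower ones. Of the 662, 407 were not called in vector against PBS fish and 246 were higher there too, beta-2 microglobulin and Ig light chain among them. Of the 228, 192 were not called there and 30 were lower there too. The total was 1611 without vector 1 (821 higher and 790 lower), 573 without vector 2 (505 and 68), 555 without vector 3 (497 and 58), 359 with the Cy3 channel alone (337 and 22) and 2342 with array weights (1048 and 1294). Leaving out vector 1 and vaccine 3 together, chosen after seeing the data, gave 2734 (1119 and 1615), so which direction held more clones depended on the arrays and weights used.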

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

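Of the tests in this part, those that split all 10 arrays into other groups for the clones changed against both controls and for the gene lists were planned, and all others were chosen only after the result they concern had been seen. Among 128 sets of 4 vaccine values, those of named clones and the means of the 20 gene lists, 5 held an array whose gap to the nearest other array, as a share of the whole range, was over the limit for 4 values (Dixon's test), where chance gives 6.4. On vaccine 3, alpha-2-macroglobulin-1 (CB509867) was at -5.18 against -5.75 to -5.66 on the other vaccine arrays (share 0.842), lysozyme g (CN442504) at -1.13 against -0.78 to -0.73 (0.881) and adipophilin (CB514104) at 0.34 against 1.04 to 1.18 (0.836). On vaccine 1, alpha enolase (CB503486) was at 1.13 against 1.57 to 1.65 (0.851), and on vaccine 4 ribosomal protein L35 (CB500108) was at 0.47 against 0.41 to 0.42 (0.91). No explanation was tested for these values.

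Chance in the grouping was tested by giving the arrays to other groups of the same sizes. For vaccine versus PBS the real grouping gave 5863 clones, and the highest other gave 3832. Only the real grouping, 1 of 35, gave as many, which is the smallest share that 35 groupings allow. This argues against chance but does not exclude it. For the clones changed against both controls, groupings of all 10 arrays gave as many as the real 890 in 1 of 100. The highest other gave 885, so this argues against chance only for the grouping as a whole. With the PBS arrays kept together, 2 of 35 groupings of the other arrays gave as many, the higher with 1332, so chance cannot be excluded for the part that parts vaccine from vector fish. For vaccine versus vector it cannot be excluded, since 2 of 35 groupings gave as many as the real 1023 clones, and the higher, with 1372, which is also the one with 1332 above, put vector 1 with vaccine 1, 2 and 4 and vaccine 3 with the other vector arrays. For vector versus PBS, with 2721 clones in the real grouping and a highest other of 0 (1 of 10 with as many), 10 groupings are too few for a test. For the gene list tests chance cannot be excluded: 10 of 100 groupings gave at least as many as the real 40 calls, up to 43. The lowest grouping still gave 13 calls. The number of lists called, and a pass of 1 list under the preset correlation, therefore say little by themselves.

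The first pattern weighed is the lower muscle lists and higher phagocyte list in fish given either plasmid. A lower share of muscle RNA alone would raise the markers of other cells alike. The phagocyte list mean minus the fibroblast list mean was 1.12 higher in plasmid than in PBS arrays (-1.67 ± 0.37, SD, n = 7, against -2.80 ± 0.16, n = 3). The exact permutation p was 0.00833, the smallest that 120 splits can give. The phagocyte rise is part of the pattern, so this p adds no independent evidence. These lists did not rise alike, but the fibroblast list lay above the pool in PBS fish (means 1.53 to 1.65). Its markers may belong to the muscle tissue, so a lower share of that tissue stays open. Over the background and scaling settings the lowest phagocyte median was 1.14 in vaccine versus PBS and 0.999 in vector versus PBS, which argues against the normalization for the phagocytes. Against an exchange of vector 1 and vaccine 3, vector 1 had an interferon list mean of -0.94 where the lowest vaccine array had 0.82. For the muscle list the normalization stays open, since its median was -0.068 with the Cy3 channel alone (quartiles -0.50 and 0.01). In the other background and scaling settings it was -0.764 to -0.642. Quantile scaling gives every array the same distribution of intensities, so it can itself remove a joint fall of bright clones. The Cy3 setting therefore cannot decide. An entry of phagocytes after plasmid injection may explain the rise of their list but was not tested by a count of cells.

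The second pattern is the interferon list, higher in vaccine than in vector fish. More leukocytes in the vaccine samples would raise their own markers too, but by as much only if both started from like levels. The interferon list mean minus each leukocyte list mean was higher on all vaccine than on all vector arrays. The smallest difference was 0.956, for the B cell list (2.44 ± 0.14, SD, n = 4, against 1.48 ± 0.02, n = 3, exact permutation p = 0.0286, the smallest that 35 splits can give). The difference was 1.46 for T and NK cells and 1.74 for phagocytes. The interferon rise is itself the pattern, so this p adds no independent evidence. More leukocytes, also those outside these lists, stay open as a cause. The lowest median of the interferon list over the background and scaling settings was 1.76, which argues against the normalization. A response of muscle or other cells to the G protein may explain the pattern, but no test of it was made.

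The third pattern is 3 clones with muscle or mitochondrial names that rose with the interferon list in vaccine against vector fish. They were put together after their values were seen, although the rule for named clones had picked CA056191 and CA051957. Cardiac troponin C (CA056191) rose by 3.70, cytochrome c oxidase subunit Vb (CA060650) by 3.93 and NADH-ubiquinone oxidoreductase AGGG subunit (CA051957) by 2.73 on the log2 scale. The 9 other clones of these names had log2 fold changes of -1.59 to -0.0081, none (0) of them past the threshold. A clone that holds another transcript than its name says could explain this, and a paralog with its own regulation stays open too, because no sequences were compared.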

How the results depend on the processing

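Of the alternatives in this part, those chosen only after the data had been seen are the filter on blank spots, loess within print blocks and leaving out vector 1 and vaccine 3 together. With the Cy3 channel alone the clones past the threshold were 2734 for vaccine versus PBS, 693 for vector versus PBS, 370 for vaccine versus vector and 359 against both controls. Asking for at least 2-fold as well gave 1256, 486, 329 and 311, which follows from the stricter call. An adjusted p under 0.10 gave 4103 for vector versus PBS and 1544 for vaccine versus vector. Array weights gave 2622 for vaccine versus vector and 2342 against both controls, and leaving out vector 1 and vaccine 3 together 2915 and 2734. Without 1 array the counts ranged from 1295 (without PBS 2; 1413 without PBS 1, 1343 without vector 1) to 3015 for vector versus PBS, from 635 (without vector 3; 647 without vector 2) to 1730 (without vector 1) for vaccine versus vector, and from 555 (without vector 3; 573 without vector 2) to 1611 (without vector 1) against both controls. The correlation of the plasmids' fold changes was 0.814 under median centring, 0.777 with the Cy3 channel alone, 0.769 without vector 1 and vaccine 3, and 0.76 to 0.815 without 1 array. Of the 60 gene list tests 3 passed with an estimated correlation, against 40.

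Directions turned for the ribosomal list in vaccine versus PBS under median centring (adjusted p = 0.0767), for the proteasome list in vaccine versus vector without vector 1 (adjusted p = 0.0043, the lowest without 1 array, where the highest was 0.977) and without vector 1 and vaccine 3 (0.00137), and for acute phase and iron genes in vaccine versus vector with 1 value per gene name (0.924). Among clones, polymeric immunoglobulin receptor (CB515236) turned to log2 0.72 in vaccine versus PBS and 0.99 in vector versus PBS, and alpha 1 type I collagen (CB494505) to 0.065 in vaccine versus PBS, with the Cy3 channel alone. Adipophilin (CB514104) turned to 0.37 in vaccine versus vector without vector 1 and vaccine 3. The cause was not tested for these. Quantile scaling of average intensity after loess changes no ratio, and the deposited table repeats the scanner's ratio. Over the other alternatives, named clones kept direction and side of the threshold in 9090 cases, lost the call in 413, gained one in 168 and turned in 4, and lists in 1545, 109, 22 and 4.

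With the replicate number as a replicate block the counts were 5067, 2726, 709 and 633, and 38 lists passed. Deviations of samples with the same number correlated at -0.219 to 0.605 across clones, over 0.1 in 3 of 9 pairs, so the numbers were not taken to pair samples. Between vector and vaccine arrays they were 0.605, 0.0502 and 0.515 for the same number, against -0.663 to 0.442 for other numbers. A shared factor between these groups is therefore not excluded. The date on which the Feature Extraction software quantified the scans sets only PBS 1 apart, so a block for it equals leaving out PBS 1. Cy3 medians of 3.59 to 6.24 times background limit what can be said of dim clones.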

Other observations

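The 7 gene lists in this part and their tests were all chosen only after clone values had been seen, and are adjusted over their own 21 tests. That adjustment does not cover the choice, so the p values in this part add no independent evidence. These lists were not tested with each array left out in turn. Metallothioneins, which bind metals, rose with the empty vector: 8 of 11 clones rose in vector against PBS fish (median log2 1.10, adjusted p = 4.04e-05, and adjusted p = 0.361 with an estimated correlation), and 3 fell in vaccine against vector fish (median -0.68, adjusted p = 0.00198, and 0.458 with an estimated correlation), while in vaccine against PBS fish 1 rose and 1 fell (median 0.23, adjusted p = 0.138). Of 23 clones for annexins and S100 proteins, which bind calcium, 12 rose and 1 fell with the vector (median 0.49, adjusted p = 2.38e-05, and 0.195 with an estimated correlation), 10 fell in vaccine against vector fish (median -0.58, adjusted p = 4e-09, and 0.063) and 8 fell in vaccine against PBS fish (median -0.19, adjusted p = 0.359). Of 40 keratin clones 21 rose and 5 fell with the vector (median 0.50, adjusted p = 0.00198, and 0.361 with an estimated correlation), 2 fell and 1 rose in vaccine against vector fish (median -0.34, adjusted p = 0.000698, and 0.361), and 15 rose and 13 fell in vaccine against PBS fish (adjusted p = 0.359).

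Of 9 clones named after stonustoxin, the zinc-binding protein A33 or the frog nuclear phosphoprotein xnf7, 8 rose and 1 fell in vaccine against PBS fish (median log2 2.03, adjusted p = 1.24e-07, and adjusted p = 0.0132 with an estimated correlation) and 8 rose against vector fish (median 2.24, adjusted p = 1.37e-15, and 0.0021), while the vector alone gave a median of 0.05 (adjusted p = 0.359). Lysosomal enzymes and the proton pump, 42 clones of which another list holds 14, rose with both plasmids: 27 up and 3 down with the vaccine (median 0.87, adjusted p = 3.78e-07, and 0.406 with an estimated correlation) and 24 up and 3 down with the vector (median 0.77, adjusted p = 1.24e-07, and 0.37). Between the plasmids their median was 0.0088 and turned to -0.0048 with the Cy3 channel alone (adjusted p = 0.359). Of 34 fatty acid binding protein clones 17 fell and 1 rose in vaccine against PBS fish (median -0.61, adjusted p = 0.00357, and 0.445 with an estimated correlation) and 8 fell against vector fish (median -0.35, adjusted p = 0.000249, and 0.361), where the vector alone gave 4 up and 3 down (adjusted p = 0.359). The values of the list meant for heat shock proteins and chaperones are left out, since its pattern also took in many clones with the unrelated name HSPC. Except for the lysosomal list, the added lists share no (0) clones with the fixed lists.

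Spots for green fluorescent protein were 1.17 to 1.33 times the blank spots in the Cy3 channel across the 10 arrays.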
